A study of Arabidopsis thaliana with 16 samples.

How the data were processed

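Khib ChIP-seq of whole seedlings was analysed from tables that the authors deposited. Per the labels, 12-day-old seedlings came from plates kept at 22 °C in long days (16 h light), formaldehyde at 1% was applied during 15 min as fixative, and the antibody was raised against Khib. Per the labels, each of the 4 genotypes had 2 ChIP and 2 input libraries as biological replicates, in 8 groups. The tables hold 1 value per genotype, so the numbers of the replicates could not be used, and how the replicates were combined and whether input reads entered is not given in the sources used here. Per the submitters' processing notes, the TAIR10 build, CASAVA, Bowtie2 2.2.5, SICER 1.0.3 and bedtools were used, with no role or order given.

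The authors deposited RPKM values (reads per kilobase of gene and of the library size) for 32548 genes in 4 tables, per the file headers. Multiplying each value by the gene's length gave whole reads within 0.01 reads for 100% of values at depths of 18.6 (Col-0), 12.0 (sant-null), 16.8 (hda6) and 38.8 (hda9) M reads. The authors deposited read counts per island for the mutant and Col-0 in 3 tables, per the file headers. They also deposited these as RPM, scaled to a library total, per the file headers. The totals behind the RPM values were 2.14, 2.04 and 1.90 times the gene depths in sant-null, hda6 and hda9 and 1.92 times in Col-0. The authors deposited a fold, the ratio of the normalized counts, in both directions, per the file headers. The authors deposited a p-value and an FDR per island and direction, per the file headers. Recomputing showed that the p-value equals the upper tail of a Poisson distribution whose mean is the other genotype's count scaled by the library totals, within 0.00216 on the log10 scale. It treats that count as known without error, so unchanged islands can be called. No organelle gene is listed among the genes used, and input libraries were not used here. No columns of per-sample values were left unmapped.

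The planned test across replicates needed a value per library, so the alternative fixed before the data were examined was used: the log2 ratio of (RPKM + 1) in the mutant and Col-0, with no test. A fold change on this scale understates that of low genes. Genes with at least 1 RPKM in at least 2 genotypes were kept, 31805 in all, and those at least 1.5-fold higher or lower were counted. Reads recovered from the RPKM steps gave the 95% interval of a fold (conditional exact, Clopper-Pearson), which covers counting error only. ChIP reads are not independent molecules, so true errors are larger. Genes were named by a rule fixed before the data were examined: the 12 highest and 12 lowest log2 ratios among genes with at least 5 RPKM in either genotype, taking the next gene with a symbol for the text, the 5 islands with the largest fold each way, the deacetylase genes and the members of each list with the largest absolute log2 ratio. The same rule restricted to protein-coding genes of at least 500 bp was added after the values were seen, because the fixed rule took mainly very short genes.

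Gene names came from a table of the TAIR10.1 assembly, used for names only, in which all 32548 loci were found and 10804 had a symbol. Lists of heat shock factors, small heat shock proteins, other heat-induced genes, flowering time, seed maturation, abscisic acid, dehydration and cold, jasmonate and defence, photosynthesis, leaf senescence, loci silenced by DNA methylation, circadian and warm-temperature growth, housekeeping, root and shoot meristem markers, deacetylases and possible SANT loci were fixed before the data were examined. Ribosomal protein and histone genes were taken by name. A list's median was placed among 10000 random lists of the same size, matched in 50 bins on the mean log2 level of the mutant and Col-0, as a description of these libraries. A list is said to lie outside the random range below percentile 2.5 or above 97.5.

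Islands were counted at the authors' FDR under 0.05 in each direction, and islands shared between tables were those overlapping by at least 1 bp (bedtools 2.31.1). Unchanged groups were simulated from the Col-0 reads at the depths of the mutants, 100 times for genes and for islands of 1 table and 20 times for shared islands. Positions of islands, of the hda6 table and later of each table, were compared between chromosomes in bins of 200 bp with 100 shifted placements. Islands of chromosomes 3 and 5 were also counted alone. This was chosen after the data were seen, because the islands of the other chromosomes followed genes of further chromosomes: the highest rank correlation with the genes of another chromosome was 0.303, 0.310 and 0.370 on chromosomes 1, 2 and 4, and 0.0432 and 0.0410 on chromosomes 3 and 5, where the islands' own genes gave 0.726 and 0.736. Chromosomes 3 and 5 still share more positions with other chromosomes than shifted placements do.

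The steps were tested on simulated data with 200 of 31805 genes altered. Of 100 doubled genes, 98 were recovered at 1.5-fold for sant-null, 97 for hda6 and 97 for hda9, and of 100 halved genes 86, 82 and 89. Of the halved genes 9, 5 and 11 could not reach 1.5-fold on the log2(RPKM + 1) scale, and the others missed were lost to counting noise. Of 31605 unchanged genes, 842, 649 and 431 passed 1.5-fold. The intervals held the true fold for 95.7%, 95.5% and 95.6% of genes. Of 100 doubled and 100 halved islands at least 99 each were recovered, while 931, 788 and 1312 unchanged islands were called.

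Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter, a filter of 5 RPKM, quantile normalization, equal medians and equal sums. For islands they were an FDR under 0.001, 2-fold, recentred folds and the 5 nuclear chromosomes. For shared islands they were larger overlaps, and for shared genes the 500 largest each way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.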

Results

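Lysine 2-hydroxyisobutyrylation (Khib), an acyl mark on histone lysines found over genes, was mapped by chromatin immunoprecipitation and sequencing in 12-day-old Arabidopsis thaliana seedlings of 4 genotypes. These were the wild type Col-0, a mutant named sant-null, and mutants of the histone deacetylases HDA6 and HDA9. The series concerns SANT-domain proteins in gene transcription and thermotolerance. Each genotype had 2 ChIP libraries and 2 input libraries, 16 samples in all, but the tables analysed here hold 1 ChIP value per genotype. No difference below has a replicate check, and all intervals cover counting error only. The deposited RPKM values of 32548 nuclear genes correspond to whole reads at depths of 18.6 M reads in Col-0, 12.0 M in sant-null, 16.8 M in hda6 and 38.8 M in hda9. A gene of 1 kb with a single read would have an RPKM of 0.0538 in Col-0 and 0.0258 in hda9, so hda9 values carry the smallest counting error. No input values were used, so a level mixes the mark with any background of the library.

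The wild-type profile was read first, to describe where Khib lies before the mutants are compared with it. The named protein-coding genes of at least 500 bp with the highest Col-0 values were DIC2, which encodes a mitochondrial dicarboxylate carrier, at 288 RPKM, the ethylene response factor gene ERF4 at 233, SRC2 at 199 and the light-harvesting chlorophyll protein gene LHB1B2 at 169. Genes without a symbol or shorter than 500 bp were left out of this ranking, and the highest protein-coding value in Col-0 was 15109 RPKM. The cold response regulator CBF2 had 147 RPKM, the zinc finger gene STZ 132 and the chaperone gene J11 117. The median over all genes was 5.63 RPKM in Col-0, 7.86 in sant-null, 7.08 in hda6 and 8.88 in hda9. The median of log2(RPKM + 1) in Col-0 was 2.73. The ratio of the 95th to the 5th percentile of gene values was 20.3 in Col-0, 31.1 in sant-null, 29.95 in hda6 and 8.45 in hda9. The 20 genes with the most reads took 16.6% of gene reads in Col-0, 10.4% in sant-null, 10.1% in hda6 and 8.53% in hda9.

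The genes of the deacetylases were examined in every genotype. HDA6 (chromosome 5, TAIR10) had 11.8 RPKM in Col-0, 11.7 in sant-null, 12.0 in hda6 and 10.9 in hda9. HDA9 had 2.33 RPKM in Col-0, 2.89 in sant-null, 2.497 in hda6 and 6.10 in hda9. These values are Khib over the gene body, so they do not check a genotype label. A set of 4 loci had been fixed before the data were examined as possible SANT-domain genes. The reference used for names does not call them so, and they are named here by locus after their values were seen. AT1G09040 (chromosome 1, 2911250 to 2915406) had 4.94 RPKM in Col-0 and 0.561 in sant-null, from 382 and 28 reads, against 6.41 in hda6 and 10.05 in hda9. Its neighbours had a median of 10.8 RPKM in sant-null. Without input values, less of the mark at this locus cannot be told apart from less DNA there. AT1G55050 (chromosome 1, 20541837 to 20545861) ranked 20th of 26207 long protein-coding genes in Col-0 at 125 RPKM and had 31.8 in sant-null, 63.0 in hda6 and 12.3 in hda9. AT2G47820 had 40.2 RPKM in Col-0, 118 in sant-null, 34.0 in hda6 and 71.2 in hda9, and AT1G09050 had 19.4, 32.4, 30.3 and 39.3 in the same order. Here and below, differences in the mark and in the DNA cannot be told apart at these loci either.

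**Figure D1:**
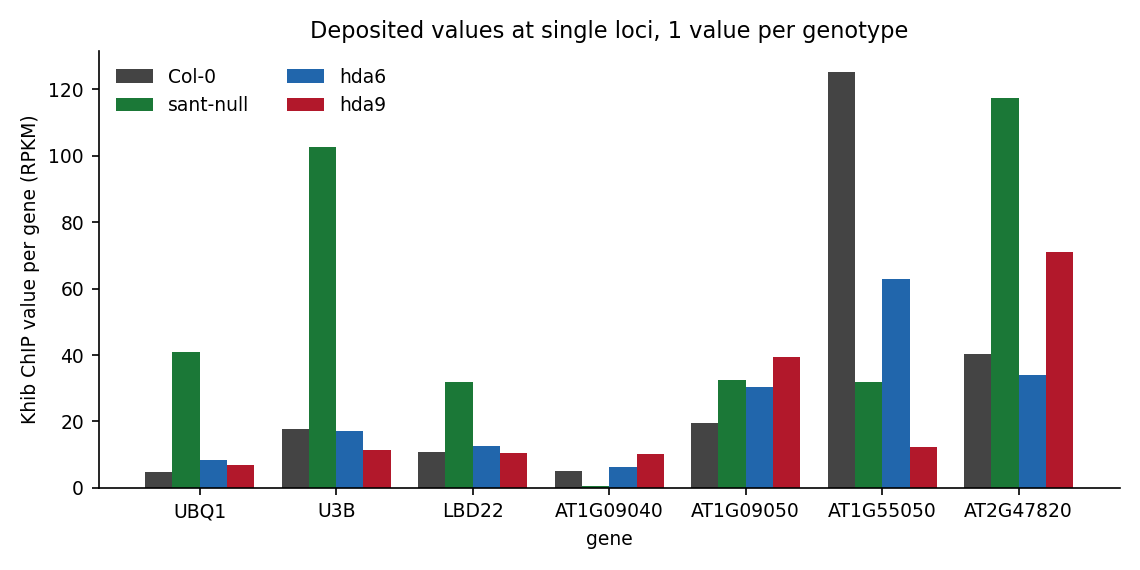
Deposited Khib ChIP values (y axis, RPKM, linear from 0) of 7 genes (x axis) in Col-0, sant-null, hda6 and hda9, 1 bar per genotype with no replicate error. UBQ1, U3B and LBD22 stand highest in sant-null (40.9, 103 and 31.7 RPKM), and AT1G09040 lies near 0 in sant-null (0.561 RPKM). No input values were used, so a difference in the mark and a difference in the DNA at a locus are not told apart.

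The comparison of sant-null with Col-0 asks how Khib differs in the sant-null mutant. The ubiquitin gene UBQ1 (AT3G52590, chromosome 3, 19505379 to 19506932) had 40.9 RPKM in sant-null against 4.77 in Col-0, a fold of 8.56 with a 95% interval of 7.13 to 10.3 from 762 and 138 reads. The U3 small nucleolar RNA gene U3B (chromosome 5, 21887966 to 21888667) had 103 against 17.84 RPKM, a fold of 5.76 (4.98 to 6.69). Among other long protein-coding genes, values were higher at ABCE3 (10.2 against 2.07 RPKM), at the chloroplast ribosomal protein gene emb2184 (8.70 against 2.18), at SYP61, which encodes a syntaxin of the trans-Golgi network (7.64 against 2.04), and at the LOB-domain genes LBD22 (31.7 against 10.7) and LBD29 (9.18 against 3.01). PLPB, ISU3, cycp3;1, SON1, BZIP53 and DOF4.5 had log2 ratios between 1.35 and 1.48. On the lower side of such genes, the peptide gene RGF3 had 1.62 against 5.23 RPKM, the arabinogalactan protein genes AGP13 and AGP24 had 10.5 against 24.4 and 10.2 against 20.97, the peptide gene CLE2 8.09 against 16.6 and the expansin gene EXPA12 9.12 against 18.9. RTFL1, MIF3, FP6, LCR59, GRP9, AIR1 and LCR58 had log2 ratios from -0.92 to -1.12.

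Over 31805 genes past the filter, the median log2 ratio of sant-null to Col-0 was 0.28, and medians of gene lists are given relative to it. Counts of list members are not centred on that median unless called centred. At 1.5-fold, 7551 genes were higher and 1913 lower, a higher share of 79.8%, which was 37.7% with equal medians and 48.4% after quantile normalization, so the balance of directions depends on the scaling. Both steps centre the ratios by construction, here and in the other mutants, so their shares do not show which direction holds. The fixed rule for named genes took mainly very short genes. Of its 12 highest, 10 were shorter than 500 bp and 9 had fewer than 50 reads in both genotypes, and all 12 of its lowest were of both kinds. A separate ranking of genes with a symbol included the microRNA genes MIR851 (16.3 against 2.34 RPKM, 36 and 8 reads) and MIR167b (32.1 against 6.41) on the higher side. On the lower side were MIR5015 (6.26 against 28.9 RPKM, 13 and 93 reads), the RALF-like peptide gene RALFL11 (8.41 against 27.1) and AGP23 (13.0 against 32.8). The long protein-coding genes named for each comparison were chosen after the values had been seen.

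Gene lists fixed before the data were examined were then set against random lists matched on level. Of 26 photosynthesis genes, 5 were lower in sant-null at 1.5-fold and 0 higher (centred, 14 and 0). Their median was -0.66 relative to all genes, at percentile 0.41 of 10000 random lists (-0.33 after quantile normalization, and -0.08 at percentile 2.81, inside the range, with the trend on the Col-0 level removed), with the chlorophyll a/b-binding protein genes CAB2 at 51.8 against 89.8 RPKM, CAB3 at 33.6 against 56.7 and LHCB2.1 at 35.1 against 55.4. Of 19 flowering time genes, 1 was higher (SPL4, 6.18 against 3.50 RPKM) and 0 lower (centred, 0 and 1), with a relative median of -0.28 at percentile 0.95, which was -0.18 at 2.525 after quantile normalization. Of 14 circadian and warm-temperature genes, 1 was higher (PRR7, 7.30 against 3.99 RPKM) and 0 lower (centred, 0 and 2), with a relative median of -0.30 at percentile 1.14, but inside the range after quantile normalization (-0.19 at 3.92) and with the trend removed (-0.14 at 5.04). The 4 possible SANT loci had 2 higher and 2 lower members (centred, 1 and 2), so that their median is a value no member has, and its percentile of 2.04 says nothing of a common direction. The heat lists, which bear on the thermotolerance named in the series, lay inside the random range. Heat shock factor genes had a relative median of 0.04 (5 of 14 higher, 1 lower; centred, 1 and 2), with HSFA6B at 3.82 against 1.59 RPKM and AT-HSFA7B at 15.1 against 25.9. Other heat-induced genes had 0.04 (4 of 22 higher; centred, 2 higher and 0 lower), with HSP90.1 at 9.49 against 3.78 RPKM and Hop3 at 6.87 against 3.005. The 15 small heat shock protein genes had -0.21, which was 0.04 after quantile normalization, with 3 higher (AT5G37670, AT1G52560 and ATHSP22.0) and 0 lower (centred, 0 and 5).

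Further lists lay inside the random range in sant-null at the main scaling. Seed maturation genes had a relative median of -0.43 (1 higher, DOG1 at 12.1 against 6.15 RPKM, and 2 lower, SESA3 and SESA1, or centred 1 and 7), at percentile 3.32, but lay outside after quantile normalization (-0.27 at 0.76) and with the trend removed (-0.13 at 1.95). Abscisic acid, dehydration and cold genes had -0.27 (LTI30 at 12.0 against 4.83 RPKM, DREB1A at 25.6 against 48.7), and jasmonate and defence genes -0.21 (4 of 28 higher and 1 lower, or centred 2 and 4, with JAZ1 at 22.5 against 10.2, WRKY70 at 14.5 against 6.77 and JAZ8 at 0.926 against 2.55). Leaf senescence genes had 0.17 (3 of 10 higher, centred 0, among them SEN1 at 16.9 against 8.98 RPKM), loci silenced by DNA methylation 0.14 (SNC1 at 13.0 against 6.83), housekeeping genes 0.10 (PP2AA3 at 5.84 against 2.92), ribosomal protein genes 0.19 (16 of 52 higher, centred 7) and histone genes -0.19 (4 of 32 higher and 1 lower, or centred 1 and 6, with HTA8 at 8.73 against 3.87 and AT1G09200 at 19.5 against 36.2). With the trend removed, these 5 medians were 0.04, -0.02, 0.16, 0.04 and 0.02 in the same order. Root markers had -0.07, shoot meristem markers -0.22 and the deacetylase pair -0.18, with 0 members higher or lower (centred, 1 root marker lower).

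In the authors' deposited table for sant-null and Col-0, islands of Khib were listed with a fold and an FDR. At an FDR under 0.05 the authors' deposited table called 4662 of 22128 islands higher in sant-null and 11796 lower, a lower share of 71.7%, which was 50.4% with the folds recentred. Recentring centres the folds by construction, here and in the other mutants, so that share does not show which direction holds. Genes at 1.5-fold went mostly the other way (7551 higher, 1913 lower), so neither split gives a general direction. Protein-coding genes overlapped by higher and lower islands on chromosomes 3 and 5 had median log2 ratios of 0.43 and -0.17 (498 and 2485 genes). Why the splits differ was not tested. The authors' deposited table had high folds at the UBQ1 island on chromosome 3 (19505001 to 19505800, fold 13.5, 610 and 62 reads), at a further UBQ1 island (19506601 to 19506800, fold 12.9), at the island covering the ends of LBD22 and U6-26, a U6 small nuclear RNA gene (chromosome 3, 4560601 to 4561200, fold 5.08), and at U3B (chromosome 5, 21887801 to 21888600, fold 4.02). The largest fold in the authors' deposited table, 20.2 at chromosome 5 (19505401 to 19505800), has no annotated gene and the coordinates of the UBQ1 island on chromosome 3. The lowest folds in the authors' deposited table were 0.333 over AT5G37360 and 0.354 over PnsB3, a gene for a chloroplast NAD(P)H dehydrogenase subunit. These calls compare 1 count per genotype and not the conditions. With unchanged islands simulated at these depths, 103 would be called higher and 704 lower. In the authors' deposited table for sant-null, islands of all chromosomes repeat positions of others, so that 92.4% of positions covered on chromosome 3 and 92.5% on chromosome 5 are also covered on chromosome 1, and on chromosomes 3 and 5, whose islands follow their own genes most closely, the authors' deposited table had 518 higher and 4033 lower.

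**Figure D2:**
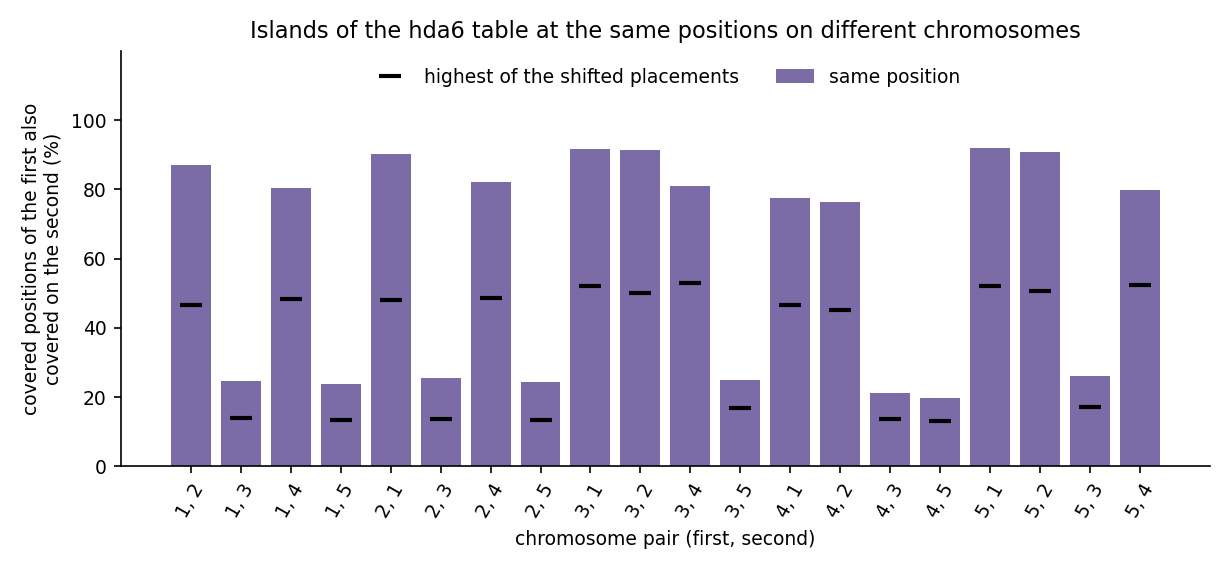
Islands in the authors' deposited table for hda6: for each pair of chromosomes (x axis), the percent of 200 bp positions covered on the first that are also covered at the same coordinates on the second (y axis, bars), with the highest of 100 placements in which the second was shifted (black marks). Bars run from 76.3% to 91.9% wherever the second chromosome is 1, 2 or 4, and from 19.9% to 26.1% where it is 3 or 5.

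The comparison of hda6 with Col-0 asks how Khib differs in a mutant of the deacetylase HDA6. Differences were smaller than in the other mutants. Among long protein-coding genes, values were higher at the peptide gene CLE20 (8.91 against 2.92 RPKM, fold 3.05 with an interval of 2.09 to 4.52), at the chloroplast thioredoxin genes TRXF1 (13.8 against 6.10, fold 2.27, 1.87 to 2.76) and ATHM2 (9.54 against 4.54), at OHP, which encodes a one-helix light-harvesting-like protein (10.3 against 4.49), at the auxin-responsive gene SAUR19 (24.3 against 11.3) and at TUF, which encodes a vacuolar ATPase subunit (8.29 against 3.71). MAPKKK21, LCR66, ATOZI1, HIPP21, emb1067 and NAC027 had log2 ratios between 0.94 and 0.97. Values were lower at RGF3 (2.77 against 5.23 RPKM), at the transcription factor genes BZIP27 (3.505 against 6.42), MYB85 (4.70 against 7.82), APL (10.4 against 16.3) and CBF2 (97.2 against 147), at CAB2 (58.1 against 89.8) and at ELP (30.3 against 47.9). RIC4, WIP4, SRS8, ORA47 and MYB94 had log2 ratios from -0.58 to -0.66.

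The median log2 ratio of hda6 to Col-0 was 0.20 over all genes. At 1.5-fold, 2888 genes were higher and 971 lower, a higher share of 74.8%, which was 33.1% with equal medians and 48.1% after quantile normalization. All 12 highest and all 12 lowest genes of the fixed rule were shorter than 500 bp. A separate ranking of genes with a symbol held mostly RNA genes of few reads, such as MIR164a (35.9 against 12.4 RPKM, 68 and 26 reads) and U5.2 (21 and 7 reads) on the higher side and MIR3932a (1 and 13 reads) and MIR5646 (16 and 43 reads) on the lower.

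Photosynthesis, ribosomal protein and housekeeping genes stood outside the matched random lists in hda6. The 26 photosynthesis genes had a median of -0.24 relative to all genes at percentile 1.04 (-0.11 with the trend removed), with 1 lower at 1.5-fold (CAB2) and 0 higher (centred, 3 and 0). LHCB2.1 had 39.3 against 55.4 RPKM, CAB1 104 against 139 and LHCB3 27.7 against 21.1. The 52 genes named as ribosomal protein genes, chosen by name with no check of the compartment, had a relative median of 0.18 at percentile 99.8, with 12 higher and 0 lower (centred, 1 and 1), among them RPL16B (11.9 against 6.27 RPKM) and RPL10B (8.62 against 4.72). The 13 housekeeping genes had 0.27 at percentile 99.5 (0.16 after quantile normalization), with 3 higher and 0 lower (centred, 0 and 0), among them the elongation factor gene AT5G60390 (31.1 against 19.2 RPKM), ACT8 (13.0 against 7.98) and EIF4A1 (16.9 against 10.8). The heat lists had relative medians of 0.05 for heat shock factors (0 of 14 higher), 0.07 for small heat shock proteins (1 of 15 higher, AT2G29500, or centred 0) and 0.10 for other heat-induced genes (0 of 22 higher). Flowering time genes had -0.06, which was 0.02 after quantile normalization, with 0 of 19 higher or lower.

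The other lists lay inside the random range in hda6. Relative medians were -0.14 for abscisic acid, dehydration and cold genes (2 higher, LTI30 and KIN1, and 1 lower, CBF2, or centred 0 and 3), 0.04 for jasmonate and defence genes (WRKY18 at 5.50 against 2.80 RPKM, JAZ8 at 1.15 against 2.55), 0.09 for leaf senescence genes (SEN1 at 16.5 against 8.98) and -0.05 for loci silenced by DNA methylation (QQS at 1.55 against 3.15, RPP4 at 5.04 against 7.57). They were -0.07 for circadian genes, -0.05 for seed maturation genes, 0.02 for histone genes, 0.10 for root markers, -0.08 for shoot meristem markers, -0.15 for the deacetylase pair and -0.16 for the possible SANT loci.

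The authors' deposited table for hda6 called 6243 of 23250 islands higher and 6696 lower at an FDR under 0.05. Its folds were small: in the authors' deposited table only 5 of the higher islands and 2 of the lower reached 2-fold as well. The highest fold of the authors' deposited table was 2.25 at CPA, which encodes a subunit of the actin capping protein (chromosome 3, 1601201 to 1601400), and the lowest was 0.480 at AT3G28899 and AT3G28900 (chromosome 3, 10902001 to 10902200). Simulated unchanged islands gave 272 higher and 358 lower calls. On chromosomes 3 and 5 the authors' deposited table had 1345 higher and 2217 lower islands.

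The comparison of hda9 with Col-0 asks the same for the deacetylase HDA9. Named genes with the highest Khib in Col-0 had among the lowest ratios. DIC2 had 70.6 RPKM in hda9 against 288 in Col-0 (fold 0.245, interval 0.235 to 0.256), ERF4 58.8 against 233, LHB1B2 41.7 against 169, CAB1 35.1 against 139, SRC2 53.1 against 199 and CBF2 40.1 against 147. CAB2, STZ, LHB1B1, J11 and ENODL2 had log2 ratios from -1.71 to -1.87, and ELP had 11.2 against 47.9 RPKM. The highest ratios were at genes with little Khib in Col-0: PROPEP3, a precursor gene of a defence signalling peptide (5.86 against 0.414 RPKM, 118 and 4 reads), ABCE3 (13.0 against 2.07), AGL51 (12.8 against 2.06), the plastid ribosomal protein gene PSRP3/1 (6.50 against 0.693), SON1 (10.7 against 1.76) and mtACP3 (8.26 against 1.29). DEG16, SAUR63, GT13, EDA35, HR1 and MYB58 had log2 ratios between 1.88 and 1.95.

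The median log2 ratio of hda9 to Col-0 was 0.48. At 1.5-fold, 13891 genes were higher and 2888 lower, a higher share of 82.8%, which was 40.9% with equal medians and 47.8% after quantile normalization. Across genes, which are not independent replicates, the ratio had a Spearman correlation of -0.74 with the Col-0 level, against -0.29 in sant-null and 0.05 in hda6. Among 10 groups ordered by Col-0 level, the lowest had a median log2 ratio of 0.99 and the highest -0.69. All 12 highest genes of the fixed rule were shorter than 500 bp, and 6 of the 12 lowest were so short. A separate ranking of genes with a symbol included the small nuclear RNA genes U5.3 (41 and 1 reads) and U5.7 (127 and 11 reads) on the higher side.

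**Figure D3:**
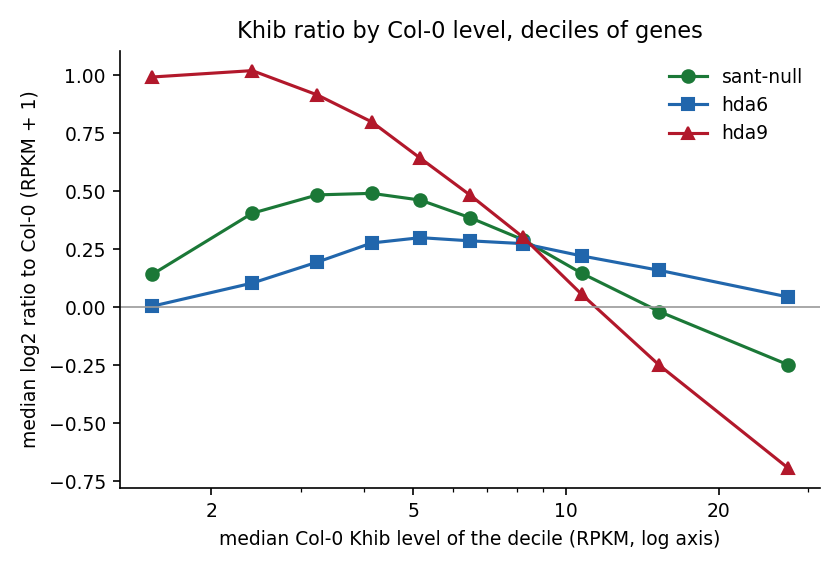
Median log2 ratio of (RPKM + 1) to Col-0 (y axis) in 10 groups of genes ordered by Col-0 level (x axis, median RPKM of the group, log axis), for sant-null, hda6 and hda9. The hda9 line runs from 0.99 in the lowest group to -0.69 in the highest, sant-null from 0.14 through 0.49 to -0.25, and hda6 stays between 0.00 and 0.30.

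Several lists were low in hda9 against random lists of like mean level, and some of these calls depend on the scaling. That level is the mean of Col-0 and hda9, so the matching need not remove the trend on the Col-0 level. Of 26 photosynthesis genes, 17 were lower and 0 higher (centred, 24 and 0), with a median of -1.31 relative to all genes at percentile 0.25, and that median was -0.45 after quantile normalization and -0.10 with the trend on the Col-0 level removed. LHCB2.3 had 20.7 against 62.1 RPKM and CAB3 19.4 against 56.7. Of 24 abscisic acid, dehydration and cold genes, 11 were lower and 2 higher (centred, 15 and 0), with a relative median of -0.95 at percentile 0.54 (-0.46 after quantile normalization, and -0.06 at percentile 3.55, inside the range, with the trend removed), among them CBF1 (24.3 against 75.7 RPKM) and the zinc finger gene RHL41 (29.4 against 80.3). Of 28 jasmonate and defence genes, 7 were lower and 2 higher (centred, 13 and 1), with -0.54 at percentile 1.99 (-0.18 with the trend removed), where PR5 had 11 against 24.2 RPKM, WRKY40 16.6 against 35.4, LOX3 19.3 against 39.4 and WRKY18 7.90 against 2.80. Of 19 flowering time genes, 1 was lower (LFY, 10.8 against 17.0 RPKM) and 1 higher (SPL4, 7.11 against 3.50, but a log2 ratio of -0.07 with the trend removed), or centred 4 and 0, with -0.36 at percentile 0.06 (-0.59 with the trend removed). Seed maturation genes had -0.89 at percentile 2.46, but -0.35 at 4.13 after quantile normalization and -0.08 at 3.95 with the trend removed (6 of 20 lower, among them SESA1 at 17.57 against 35.6 RPKM, and 1 higher, or centred 13 and 0), and the 5 shoot meristem markers -0.50 at percentile 2.08, with 0 members past 1.5-fold (centred, 2 lower). The 4 possible SANT loci had 3 higher members and 1 lower, AT1G55050 (centred, 0 and 1), at percentile 99.1, which was 93.7 with the trend removed.

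The heat lists lay inside the random range in hda9 at the main scaling. HSP90.1 had 12.5 against 3.78 RPKM, AT5G48570 7.83 against 2.48 and Hop3 8.51 against 3.005 among other heat-induced genes, of which 8 of 22 were higher and 0 lower (centred, 3 and 3). Their relative median was -0.18 at percentile 68.9, which was 0.19 at percentile 96.0 after quantile normalization, and with the trend removed the list lay outside at percentile 99.5. Heat shock factor genes had -0.26 (4 of 14 higher, 3 lower; centred, 1 and 4), with HSFA6B at 5.19 against 1.59 RPKM and AT-HSFA7B at 13.7 against 25.9. Small heat shock protein genes had -0.52 (3 of 15 higher, 2 lower; centred, 0 and 6), with AT1G07400 at 14.7 against 26.6 RPKM and HSP17.4 at 18.3 against 30.8, though its log2 ratio was 0.15 with the trend removed. Inside the range were also housekeeping genes at -0.13 (UBQ10 at 38.5 against 76.6 RPKM, but a log2 ratio of 0.07 with the trend removed), circadian genes at -0.31, histone genes at -0.58 (HIS1-3 at 8.77 against 2.67, AT1G09200 at 16.8 against 36.2) and root markers at -0.53. Histone genes had -0.11 after quantile normalization and 0.02 with the trend removed, and root markers -0.17 and -0.14. The relative medians of ribosomal protein genes (0.12, 26 of 52 higher and 2 lower, centred 4 and 6), leaf senescence genes (0.02, 3 of 10 higher, centred 0 and 1 lower), loci silenced by DNA methylation (0.19, 4 of 7 higher, centred 0) and the deacetylase pair (0.01) turned to -0.09, -0.08, -0.18 and -0.02 after quantile normalization.

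**Figure D4:**
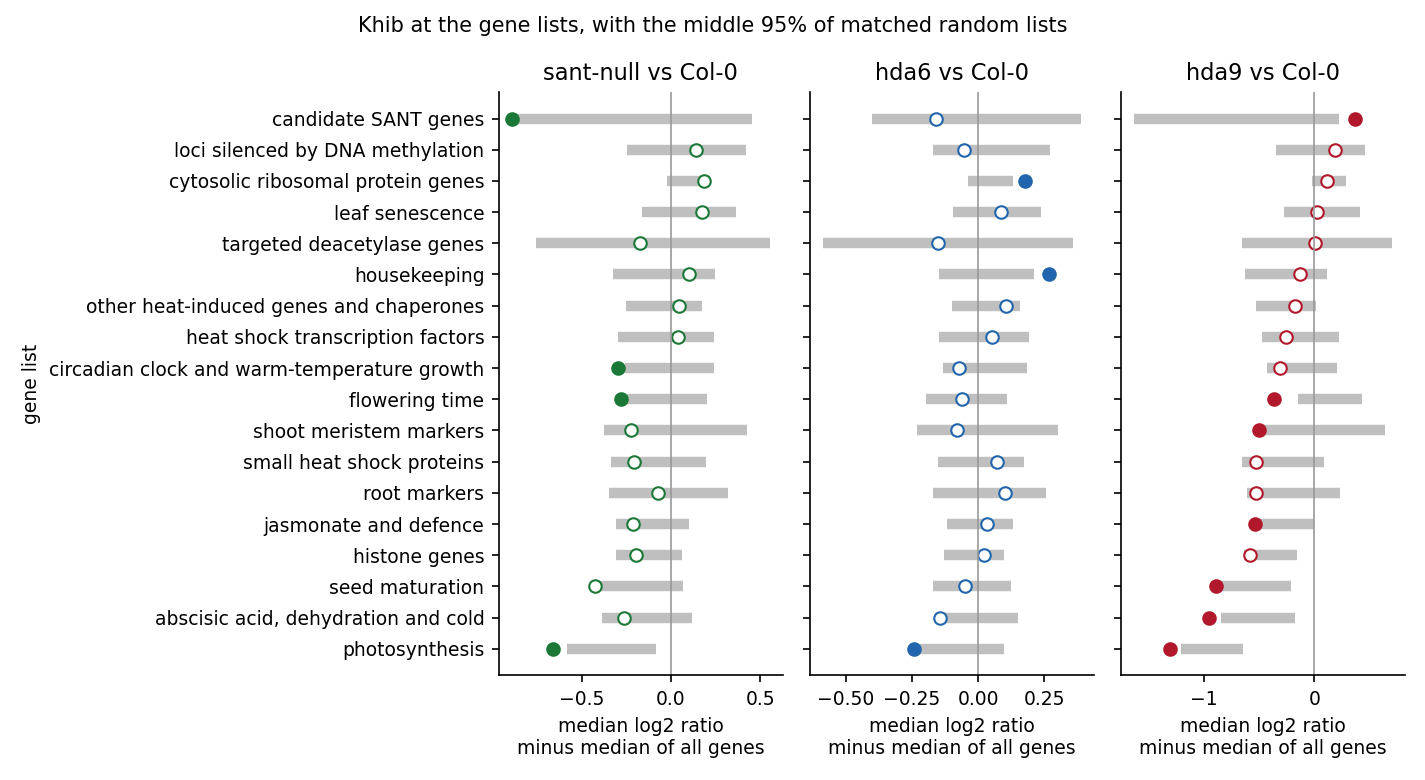
Median log2 ratio of each of 18 gene lists minus the median of all genes (x axis, scale differs between panels) in sant-null, hda6 and hda9 against Col-0, with the middle 95% of 10000 random lists matched on level (grey bars). Filled points lie outside the bars: photosynthesis genes do in all 3 panels (-0.66, -0.24 and -1.31), though in sant-null not with the trend on the Col-0 level removed (percentile 2.81).

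The authors' deposited table for hda9 called 4262 of 21060 islands higher and 14473 lower at an FDR under 0.05, a lower share of 77.3%, which was 47.5% with the folds recentred. Genes at 1.5-fold again went mostly the other way (13891 higher, 2888 lower), and why was not tested. Protein-coding genes overlapped by higher and lower islands on chromosomes 3 and 5 had median log2 ratios of 0.59 (76 genes) and -0.26 (3287 genes). The highest fold in the authors' deposited table was 3.85 over AT4G30800 (chromosome 4, 15002001 to 15002400), and SON1 (2.96), the sterol biosynthesis gene DWF5 (3.08) and the potassium antiporter gene KEA4 (2.98) followed AT1G50880 (3.20). All of these lie on chromosomes 1, 2 and 4, whose islands also follow genes of other chromosomes. At SON1 and KEA4 another chromosome had an island at the same position. On chromosomes 3 and 5 the highest fold in the authors' deposited table was 2.77 at EXT13 (chromosome 5, 13434401 to 13435000). The lowest folds in the authors' deposited table were 0.310 at the phospholipase gene PLC1 and 0.316 at the phloem transcription factor gene APL, and AT1G55050 had 0.324 (chromosome 1, 20542801 to 20544800). Simulated unchanged islands gave 1325 higher and 14.8 lower calls. On chromosomes 3 and 5 the authors' deposited table had 88 higher and 5068 lower islands.

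The 18 lists were compared in 3 mutants, 54 comparisons in all, so that some lie outside the middle 95% by chance; in simulated data 5%, 7% and 6.5% of random lists did so for sant-null, hda6 and hda9.

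Overlaps between the mutants were counted last, to see whether the same genes differ from Col-0. ABCE3 and SON1 stood among the highest long protein-coding genes in both sant-null and hda9, RGF3 among the lowest in both sant-null and hda6, and CAB2, CBF2 and ELP among the lowest in both hda6 and hda9. At 1.5-fold, sant-null and hda9 shared 6423 higher and 949 lower genes, where independent lists would share 3298 and 174 and unchanged groups against the same Col-0 reads 108 and 68.6. The sant-null and hda6 lists shared 1833 higher and 437 lower genes (independent 686 and 58.4, unchanged 116 and 95.5), and the hda6 and hda9 lists 1792 and 186 (independent 1261 and 88.2, unchanged 112 and 64.8). The balance depends on the scaling, since with equal medians the shared higher and lower genes numbered 1663 and 2948 for sant-null and hda9, 497 and 1092 for sant-null and hda6, and 388 and 617 for hda6 and hda9. Of the 500 genes highest in each, sant-null and hda9 shared 174, sant-null and hda6 156 and hda6 and hda9 90, all fewer than unchanged groups gave (201, 176 and 219). Of the 500 lowest, they shared 79, 150 and 44 against 153, 131 and 168. Independent lists of 500 genes would share 7.86. In unchanged groups, lists of a fixed size are filled by counting noise alone, in part the noise of Col-0, which both lists share. Differences found in a single mutant would displace such genes, so fewer shared genes than in unchanged groups do not show that the sharing is noise. The covariance of log2 ratios was 0.233 for sant-null and hda9, 0.108 for sant-null and hda6 and 0.0629 for hda6 and hda9, against 0.0185 in unchanged groups. Pearson correlations across genes were 0.66, 0.56 and 0.25, against 0.51, 0.43 and 0.57 in unchanged groups. Those groups vary by noise only, so a lower correlation between mutants does not show less sharing. Col-0 gave 1 value and could not be split, so its part in these overlaps was not separated.

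Among islands, 10951 of the 11796 lower in sant-null overlapped by at least 1 bp an island lower in hda9 in the authors' deposited tables, where independent lists would give 8105. For higher islands that number was 2348, against 643. In the authors' deposited tables sant-null and hda6 shared 2682 higher and 5904 lower islands (independent 998 and 3397). The authors' deposited tables had 1811 hda6 higher islands overlapping hda9 higher islands and 2193 overlapping hda9 lower islands, and 6038 shared lower islands (independent 789 higher and 4601 lower). Of all hda9 islands, 68.7% were called lower and 20.2% higher, so the larger number of 2193 does not show a tendency to the opposite direction. Unchanged islands, simulated over those with identical bounds in both tables, shared at most 59.9. Most shared higher islands lie on chromosomes 1, 2 and 4: on chromosomes 3 and 5 the authors' deposited tables had only 43 for sant-null and hda9, 318 for sant-null and hda6 and 27 for hda6 and hda9.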

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

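The settings with protein-coding genes of at least 500 bp, with the trend on the Col-0 level removed, with chromosomes 3 and 5 alone, with quantile normalization of the lists and with equal medians for shared genes were chosen after the data were seen. No gene at least 1.5-fold higher or lower among those picked by rank, the deacetylase genes and the possible SANT loci took the opposite sign under the settings that kept it. Of 123 list members checked in the same way after the values were seen, 11 did, all in hda9, after quantile normalization (6) or with the trend removed (11): PRR9, SPL4, HSFA1D, UBQ10, NYC1, QQS, IBM1, WOX5, AT4G21870, HSP17.4 and AT1G52560. No list passed from one side of the random range to the other. Of 162 list values under other settings, 149 stayed on their side of the limits, 10 came inside the range (photosynthesis, flowering, circadian and possible SANT lists in sant-null, and abscisic acid, seed maturation and possible SANT lists in hda9) and 3 left it (seed maturation in sant-null and other heat-induced genes in hda9). For cases where a value moved, the cause was not tested, except where a filter or a choice of chromosomes leaves fewer items to count. No paired analysis was possible because the tables hold 1 value per genotype and carry no replicate number. For the same reason the replicate block, leaving out each replicate, a fit with only the compared genotypes, an adjusted p with a 1.5-fold limit, camera with an estimated correlation, fry, edgeR and DESeq2 were not run, nor was ChIP minus input, since no input values were used. Depth limits sant-null most, at 12.0 M reads.

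For genes higher and lower in sant-null, hda6 and hda9, a pseudocount of 5 RPKM gave 2185 and 629, 780 and 154, and 6448 and 1887. A pseudocount of 0.1 RPKM gave 4437 and 1664 in hda6. A filter of 5 RPKM gave 930 lower in sant-null, 246 lower in hda6 and 8329 higher in hda9. Quantile normalization gave 2363 and 1142 higher in sant-null and hda6 and 4494 higher and 4903 lower in hda9. Equal medians gave 2624 and 4330, 962 and 1947, and 4903 and 7095, and equal sums over genes 1731 lower in hda9. Long protein-coding genes alone gave 826 lower in sant-null and 1663 higher and 265 lower in hda6. With the trend on the Col-0 level removed, 2227, 1081 and 1972 were higher and, in hda6, 1476 lower. The Col-0 median of log2(RPKM + 0.1) was 2.52.

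For islands of the authors' deposited tables in the same order, requiring 2-fold as well left 63 and 189, 5 and 2, and 105 and 1502. An FDR under 0.001 left 3499 and 4207 in hda6. Recentred folds gave 7664 and 7798 in sant-null and 9135 and 8277 in hda9. Chromosomes 3 and 5 alone held 518 and 4033, 1345 and 2217, and 88 and 5068. Lists outside the random range in sant-null were 2 after quantile normalization, against 4 with the possible SANT loci, whose members go both ways.

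For shared genes, higher and lower, the 500 largest gave 156 and 150 for sant-null and hda6, 174 and 79 for sant-null and hda9, and 90 and 44 for hda6 and hda9. Equal medians gave 497 and 1092, 1663 and 2948, and 388 and 617. Shared islands on chromosomes 3 and 5 numbered 318 and 2118, 43 and 4023, and 27 and 2189 for the same pairs, and a reciprocal overlap left 962 higher for hda6 and hda9.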

Other observations

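All tests of explanations below were chosen after the result was seen, except the thinning of hda9 reads and the correlation of folds between chromosomes 3 and 1, and the test of UBQ1 alone was added after the test of the 3 families had come out.

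Some classes of RNA genes had other median ratios than all genes, with no test of the difference. The 3279 lncRNA genes had relative medians of -0.11, -0.08 and 0.05 in sant-null, hda6 and hda9 (0.03, -0.005 and 0.13 after quantile normalization). Antisense RNA genes had 0.21, 0.12 and -0.03 (0.35, 0.13 and 0.59). Small nuclear RNA genes had 0.03, 0.10 and -0.30 (0.16, 0.06 and 0.29), so in hda9 both classes took the opposite sign. Transfer RNA genes had a median of 20.2 RPKM in Col-0, 45.7 in sant-null, 35.7 in hda6 and 38.7 in hda9, and their median log2 ratios were 0.56, 0.50 and 0.19 above those of all genes, with the same sign after quantile normalization (0.78, 0.49 and 1.00). Of 559 such genes, 361 were at least 1.5-fold higher in sant-null, 313 in hda6 and 306 in hda9. MicroRNA genes had 3.93 RPKM in Col-0, 3.15 in sant-null, 3.35 in hda6 and 6.67 in hda9, with relative medians of -0.59, -0.38 and -0.19. Small nucleolar RNA genes had 3.13, 1.92, 2.90 and 4.55 RPKM, with relative medians of -0.53, -0.18 and -0.08. The 4 ribosomal RNA genes had medians of 11854, 7579, 6579 and 4839 RPKM and took 4.04%, 2.39%, 2.35% and 1.57% of gene reads, and their relative medians of -0.94, -0.90 and -1.79 became 0.00 after quantile normalization. That step gives 0 to any gene of unchanged rank, so the 0.00 does not show that the difference comes from the scaling. Transfer RNA, small nucleolar RNA and microRNA genes have median lengths of 73, 92 and 145 bp, so their values rest on few reads. Small nucleolar RNA and microRNA genes also have lower RPKM, so they rest on fewer reads still. Transfer RNA genes occur in near-identical copies that can share reads, which was not checked here.

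Gene values lay closer together in hda9 than in Col-0, where high genes such as DIC2 and CAB1 had among the lowest ratios. Deeper sequencing does not account for it, since thinning hda9 to the Col-0 depth left the ratio of the 95th to the 5th percentile at 8.61, against 8.45 before and 20.3 in Col-0. Background reads spread evenly over genes are argued against at the low end: the 1294 protein-coding genes lowest in Col-0 had a median of 3.67 RPKM in hda9 (quartiles 2.53 and 4.78), where the line through the upper bins would put them at 7.94. Background that follows mappability or sequence, as an input library would show it, remains open, because the rank correlation of -0.736 between ratio and Col-0 level could come from it or from less Khib at the strongest genes of the hda9 mutant, and no input values were used. That biological difference was not tested, and the explanations cannot be told apart here.

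Islands in the authors' deposited tables occur at the same positions on different chromosomes. On chromosome 1 of the hda6 table, 87.1% of covered positions were covered on chromosome 2 too, against at most 46.6% in 100 shifted placements (86.0% and 48.2% in the sant-null table, 86.4% and 55.4% in the hda9 table). Duplicated sequence need not lie at the same coordinates. This coincidence is itself the pattern to be explained, however, and no sequence was examined, so it does not decide on duplicated sequence. The sant-null folds of 2260 chromosome 3 islands correlated with those of chromosome 1 islands at the same position (Pearson 0.563, shifted placements -0.115 to 0.139), which is consistent with reads of other chromosomes having been counted under chromosome 1. Chromosomes 3 and 5 are not free of the pattern, since 26.1% of positions covered on 5 in the hda6 table were covered on 3, against at most 17.0% when shifted, so results from them alone are affected too. No biological explanation was tested, and the step at which this arose is not given in the sources used here.

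UBQ1 and U3B had far higher values in sant-null than in the other genotypes, and U6-26 had 21.5 RPKM against 8.52 in Col-0, though 24.5 in hda9. LBD22, which overlaps the same higher island as U6-26, had 31.7 RPKM in sant-null, 10.7 in Col-0, 12.5 in hda6 and 10.6 in hda9. Vectors for genome editing often carry promoters of ubiquitin and U6 genes, so extra copies of these regions in the sant-null plants may add reads, although the labels name no such vector. Neighbouring genes do not settle it: 12 chosen to lie outside the higher islands were 0.34 above the median of all genes and 0.36 with the 3 overlapping genes put back, both within 1.5-fold. LBD22 (1.48) and AT5G53905 (1.48) were past it, but they overlap the higher islands, where extra copies would add reads too. AT5G53910, outside the islands, was past it as well (1.33, on 53 and 25 reads), and had 1.60 in hda9. The other 26 UBQ, U3 and U6 genes do not decide on a common change of the 3 families. Their median log2 ratio was 0.51 (quartiles 0.07 and 0.85), within 1 of the U6-26 value of 1.24, which rests on 26 and 16 reads. The higher island there (fold 5.08, 367 and 100 reads) lies mostly outside U6-26, so the gene value does not represent it. U3D, the only other U3 gene here, had -0.21 on 108 and 195 reads, which goes against a common change for U3B (2.46). For UBQ1 alone it is argued against, because 12 other ubiquitin genes had a median of 0.22 and reached at most 0.91 (UBQ9), against 2.86, and a change of Khib at these loci in the sant-null genotype remains open and was not tested.

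AT1G09040, among the possible SANT loci, ranked 25798th of 26207 long protein-coding genes in sant-null at 0.561 RPKM, where its neighbours had a median of 10.8 RPKM, and 15023rd in Col-0, where they had 7.50. AT1G55050 ranked 20th in Col-0, 283rd in sant-null, 81st in hda6 and 4810th in hda9, and AT2G47820 ranked 264th, 18th, 451st and 11th. AT1G55050, AT2G47820 and AT1G09050 lay above the median of their neighbours in every genotype. For AT1G55050 that median was 3.82 RPKM in Col-0, against 125 at the locus, and 8.74 in hda9, against 12.3. For AT2G47820 it was 14.8 RPKM in sant-null, against 118, and 13.9 in hda9, against 71.2. Without input values, a difference in the mark at these loci cannot be told apart from a difference in the DNA there.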
